A study of Homo sapiens with 9 samples.

How the data were processed

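RNA was measured in 9 cultures of LNCaP cells, 3 each labelled vehicle, R1881, and gedunin plus R1881. Total RNA was extracted with Trizol and biotin-labelled cRNA was prepared, per the labels' protocols. The authors deposited an intensity per probe set and array on a linear scale, between 8.63 and 20189 over all arrays, summarised with RMA per the submitters' processing notes. RMA subtracts background, quantile-normalises the arrays and summarises probes by median polish; its software and version are not given in the sources used here. Because RMA makes the arrays' distributions nearly alike, a change of total RNA per cell cannot be seen in these values. Between 492 and 960 probe sets had exactly equal deposited values in a pair of arrays (no tolerance), and 98, 57 and 105 genes had 3 equal values within the groups labelled vehicle, R1881 and gedunin plus R1881. The source of these ties was not tested. Precision is limited by the number of arrays, 3 per group.

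Deposited intensities were taken to log2. Of 22277 probe sets, 62 were controls, 19064 had 1 gene symbol in the platform annotation, 1043 had several and 2108 had none. Gene identifiers were compared with a table of human RefSeq genes (GRCh38.p14), used for names only: 12 probe sets with 1 symbol had no match there and kept the annotation's symbol, and 0 symbols changed. Probe sets with several symbols or none are named by no gene. Each of the 11963 genes was represented by the probe set with the highest mean over the 9 arrays; 4310 genes had several. Genes with probe sets called in both directions numbered 19 of 3977, 9 of 3554 and 13 of 3539 genes with a called probe set in the first, the second and the third comparison. Of the genes chosen by the rule for naming, 50, 54 and 51 had several probe sets, whose folds lay over 1.5 times apart for 17 in each comparison; 8, 8 and 12 of these had a probe set that was not called.

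Groups were compared with limma 3.58.1 in R 4.3.3: lmFit with 1 coefficient per group over all 9 arrays, contrasts, and eBayes without trend, which added 6.38 prior degrees of freedom. Tests are two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The first comparison is labelled R1881 minus labelled vehicle, the second gedunin plus R1881 minus labelled R1881, and the third gedunin plus R1881 minus labelled vehicle. A moderated F-test covered all 3 groups. Errors of log2 fold changes are standard errors from limma, and errors of intensities and scores are SDs over 3 arrays. On simulated data with 50 changed genes per fold size among 11963, calls recovered 40%, 52% and 52% of 1.2-fold changes in the first, the second and the third comparison and 100% of 1.5-fold, 2-fold and 4-fold changes, with 5, 9 and 8 false calls.

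Before the data were examined, 29 gene lists were written from background knowledge, as were the tests, the rule for naming genes and the processing alternatives. The lists cover androgen-induced and androgen-repressed genes, heat shock genes, HSP90 paralogs and co-chaperones, the unfolded protein response, ATF4-linked amino acid genes, tRNA synthetases, NRF2-linked antioxidant genes, replication, mitosis, cholesterol, fatty acid and polyamine metabolism, glycolysis and hypoxia, respiratory chain, p53 targets, apoptosis regulators, proteasome, ribosome biogenesis, immediate early genes, metallothioneins, interferon-stimulated genes, autophagy and lysosome, and pioneer factors and coregulators of steroid receptors. Further lists hold neuroendocrine, basal epithelial, fibroblast, leukocyte and luminal markers. Each list was tested against the other genes with camera at its preset correlation of 0.01, adjusted over the 29 lists. Camera with a correlation estimated from the residuals, which also lowers the degrees of freedom of its test, and fry, which tests whether a list's genes move on balance one way, were alternatives. In each list that passed camera, the median, the mean and the test had 1 sign. List scores are the mean log2 value of the measured members of a list per array, compared by an exact two-sided permutation test.

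Named genes follow this rule. For the first and second comparisons it takes the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, and for the third the 5 largest of each. It adds up to 4 called members of each list with the largest change, and 15 fixed genes whatever their values. Of these 15, 11 were measured by a probe set with 1 symbol, and the other 4 are not analysed here. Where the lower group of a named gene averaged under 52.4, the lowest array median, its fold is approximate, also where this is not repeated. Overlaps between comparisons that share arrays are set beside 100 simulations without effects and beside the overlap of independent lists, the product of both counts divided by the genes tested. For the slope between comparisons, genes called on 2 arrays per group were measured on the arrays left out, in 3 folds. A test added after the data had been seen chose genes with 1 vehicle array and 2 arrays of each other group, took the other vehicle arrays for the separate differences, and averaged all such choices within each fold. Slopes with no effects came from 200 simulations of noise with each gene's residual SD.

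The alternatives were other ways of combining probe sets, omission of the dimmest 40% of genes, median centring, a second quantile normalisation, an offset of 16 before log2, another variance model, array weights, the 6 compared arrays alone, a fold threshold, the replicate number as a block, and each array left out in turn. The count of genes apart from both other groups, the exchange of the labels vehicle and R1881 and the slopes by direction were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.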

Results

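Gene expression was measured on Affymetrix arrays in LNCaP cells, a human prostate cancer line that was established from a lymph node metastasis and responds to androgen. By the labels, cells spent 2 days in medium with 10% charcoal-stripped serum, which is depleted of steroid hormones. They then received vehicle, 1 nM R1881 (methyltrienolone, a synthetic androgen), or 1 nM R1881 together with 20 µM gedunin, a plant limonoid described as an inhibitor of HSP90 function. Each treatment had 3 arrays marked as biological replicates, 9 arrays in all. The labels give a treatment of 24 h for every group, except that the titles of the arrays labelled R1881 give 6 h while their descriptions and protocols give 24 h. The time of that group is therefore not settled by the labels.

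The median intensity of an array lay between 52.4 and 54.5 over 22277 probe sets. Log2 values of 11963 genes correlated with r between 0.996 and 0.998 within groups and between 0.972 and 0.983 across groups, where r is taken across genes, which are not independent replicates. The first principal component held 54% of the variance and set the arrays labelled vehicle and labelled R1881 at opposite ends, with the gedunin arrays in between. The second held 34% and separated the gedunin arrays from the rest. The 3' minus 5' signal of the ACTB and GAPDH control probe sets, a sign of RNA integrity, differed between group means by -0.05 to 0.04 on the log2 scale for ACTB and by -0.02 to 0.00 for GAPDH. The lowest exact two-sided permutation p was 0.3, where 3 arrays against 3 allow 0.1 at best. Marker lists of basal epithelial cells, fibroblasts, leukocytes and neuroendocrine cells passed camera in none of the 3 comparisons, with a lowest adjusted p of 0.263. Fry, an alternative test, called the neuroendocrine list in all 3 comparisons and the fibroblast list in the first and the second.

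The first comparison asks what androgen does to hormone-starved cells. FKBP5, a co-chaperone gene strongly induced by androgen in prostate cells, measured 45.1 ± 3.15 on the arrays labelled R1881 and 1810 ± 147 on the arrays labelled vehicle (intensity, mean ± SD, n = 3), 40.2-fold lower. KLK2 was 20.2-fold lower, TMPRSS2 16.9-fold lower and KLK3, which encodes prostate-specific antigen, 8.84-fold lower. ACKR3, BCHE, UGT2B17 and CAMK2N1, described as repressed by androgen, were 25.2-fold, 20.0-fold, 18.2-fold and 17.8-fold higher on the arrays labelled R1881. For 8 of the 20 largest changes in this comparison (FKBP5, ACKR3, BCHE, UGT2B17, GASK1B, MAF, ORM1 and AZGP1) the lower group averaged under 52.4, the lowest median of an array. Such values cannot be told from background here, so these folds are approximate. These directions are opposite to the androgen response described for these genes, so groups are named by their labels throughout and every direction involving the groups labelled vehicle or R1881 rests on labels that the androgen genes contradict.

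**Figure D1:**
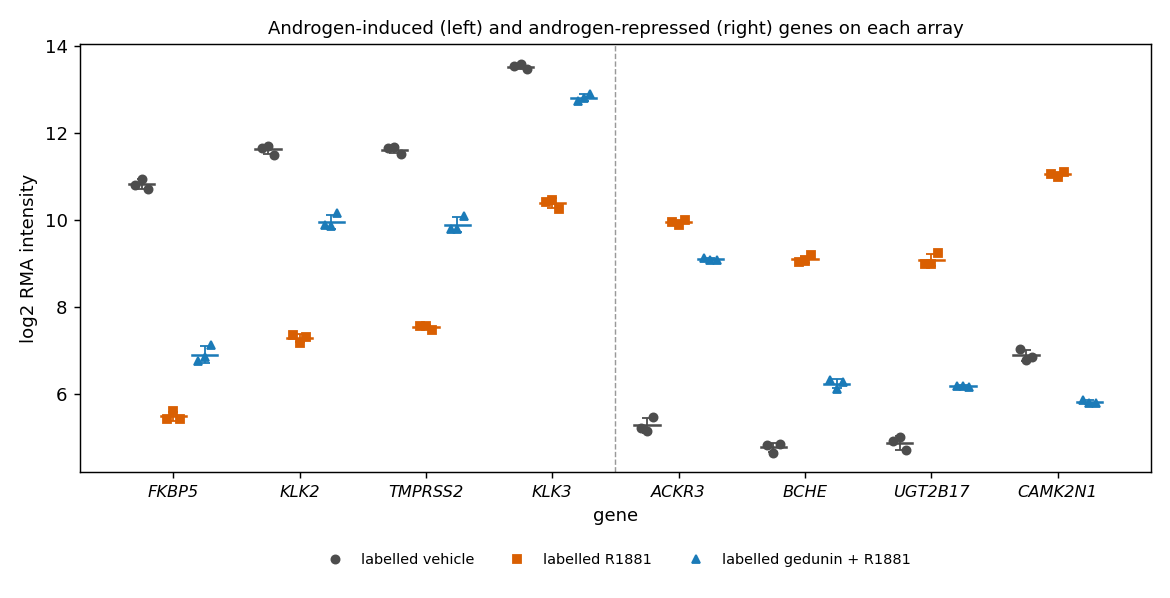
Log2 RMA intensity (vertical axis) of 8 genes (horizontal axis) on each of the 9 arrays, with points for arrays, long bars for group means and error bars for the SD (n = 3). The 4 androgen-induced genes on the left are lowest on the arrays labelled R1881, and the 4 androgen-repressed genes on the right are highest there, with CAMK2N1 lowest on the gedunin arrays.

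In limma with Benjamini-Hochberg adjustment, 3624 of 11963 genes differed between the arrays labelled R1881 and labelled vehicle, 2000 higher and 1624 lower, of which 155 and 242 changed at least 2-fold. The largest falls also included NCAPD3, a condensin II subunit (log2 fold change -4.16 ± 0.07, SE, adjusted p = 4.01e-13), EAF2 (-4.05), MAF (-3.99), NDRG1 (-3.85), GNMT (-3.84), ORM1 (-3.80) and AZGP1 (-3.64). The largest rises also included GASK1B (4.40 ± 0.11, adjusted p = 6.95e-12), MANEA (3.65), PEG3 (3.24), BARD1 (3.20), UGT2B15 (3.19) and DDC, which encodes aromatic L-amino acid decarboxylase (2.95). The UGT2B genes are near-identical paralogs, as are KLK2 and KLK3 in part, and their probe sets cannot fully separate them. MYC was 2.06-fold higher on the arrays labelled R1881, against 3 equal deposited values on the arrays labelled vehicle. ATF3 and SESN1 also had 3 equal values there, and UGT2B15 on the gedunin arrays. HMOX1 (0.03 ± 0.13, SE), DDIT3 (0.00 ± 0.08), CDKN1A (0.09 ± 0.06) and HSP90AB1 (0.09 ± 0.05) did not pass. Values are those of the brightest probe set of a gene, and other probe sets of some genes differed widely. The log2 fold change furthest from the value used was 0.17 for DDC, 0.20 for UGT2B15, -0.73 for MAF, -2.48 for TMPRSS2, -0.13 for FASN, -0.38 for ELOVL5 and -0.01 for TYMS, and the KLK2 probe sets ran from -5.48 to -1.69.

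Among the androgen-induced genes, 34 of 36 measured members were lower on the arrays labelled R1881 and 0 higher, also 34 and 0 adjusted over the list alone (median log2 fold change -2.45, camera adjusted p = 1.1e-40). Of the 12 androgen-repressed genes, 10 were higher and 0 lower, also 10 and 0 adjusted over the list alone (median 3.07, camera adjusted p = 1.17e-15). The mean log2 value of the induced list was 6.65 ± 0.003 on the arrays labelled R1881 and 8.99 ± 0.053 on those labelled vehicle (SD, n = 3), with an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 allow. Luminal markers split, with 4 of 12 higher and 5 lower, also 4 and 5 adjusted over the list alone. The keratin genes KRT8 (-2.98) and KRT18 (-2.14) fell beside KLK2 and KLK3, and the list passed camera at adjusted p = 0.0365 (adjusted p = 0.323 with an estimated correlation).

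Endoplasmic reticulum chaperones and unfolded protein response genes were lower on the arrays labelled R1881, with 21 of 24 lower and 0 higher, also 21 and 0 adjusted over the list alone (median -0.80, camera adjusted p = 1.39e-18). DNAJB9, an ER co-chaperone, fell by 2.75 on the log2 scale, HERPUD1 by 1.68, MANF by 1.49 and SDF2L1 by 1.48. Cholesterol synthesis and uptake genes followed, with 14 of 18 lower and 1 higher, also 14 and 1 adjusted over the list alone (median -0.69, camera adjusted p = 3.92e-09). INSIG1 was at -2.07, IDI1 at -1.71 and HMGCS1 at -1.43, while TM7SF2 was higher at 1.01. Of 13 fatty acid synthesis genes 9 were lower and 3 higher, 9 and 4 adjusted over the list alone (camera adjusted p = 0.000617, adjusted p = 0.143 with an estimated correlation), with FASN, the fatty acid synthase, at -1.72, ELOVL5 at -1.29 and FADS2 at -1.23. Polyamine genes had 5 of 11 members lower and 1 higher, 6 and 2 adjusted over the list alone (camera adjusted p = 0.00754, adjusted p = 0.153 with an estimated correlation). They included SMS, spermine synthase, at -2.64 and ODC1, ornithine decarboxylase, at -2.48. ATF4-linked amino acid genes had 16 of 25 lower and 1 higher, 17 and 1 adjusted over the list alone (median -0.35, camera adjusted p = 9.76e-07), and tRNA synthetases 8 of 16 lower and 2 higher, 9 and 3 adjusted over the list alone (camera adjusted p = 0.00619, adjusted p = 0.285 with an estimated correlation).

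Mitosis genes were higher on the arrays labelled R1881, with 39 of 44 higher and 0 lower, also 39 and 0 adjusted over the list alone (median 0.77, camera adjusted p = 1.04e-20). TOP2A, topoisomerase II alpha, rose by 1.74 ± 0.13 (SE), PBK by 1.58, DLGAP5 by 1.34 and RACGAP1 by 1.27. On the arrays labelled vehicle DLGAP5 lay under the lowest array median, so its rise is approximate. Replication genes had 20 of 37 higher and 1 lower, 22 and 2 adjusted over the list alone (median 0.33, camera adjusted p = 3.15e-06, adjusted p = 0.0794 with an estimated correlation), among them TYMS, thymidylate synthase, at 1.36 and GINS1 at 1.12. Respiratory chain subunits had 19 of 60 higher and 2 lower, 22 and 2 adjusted over the list alone (median 0.10, camera adjusted p = 0.000617, adjusted p = 0.555 with an estimated correlation), with NDUFB4 at 0.68. Proteasome subunits had 12 of 30 lower and 3 higher, 14 and 3 adjusted over the list alone (median -0.10, camera adjusted p = 0.0308, adjusted p = 0.648 with an estimated correlation), with PSMD8 at -1.13.

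In this comparison 13 of 29 lists passed camera with its preset correlation, 4 higher and 9 lower, and 6 passed with an estimated correlation: the androgen-induced, androgen-repressed, unfolded protein response, amino acid, mitosis and cholesterol lists. With the estimated correlation their camera adjusted p was 0.0037, 0.00185, 0.00163, 0.0235, 0.0235 and 0.028 in this order, far weaker than with the preset one. Leaving out vehicle replicate 2 or R1881 replicate 1 ended the calls of the proteasome list (adjusted p = 0.112 and 0.0796) and of the luminal list (adjusted p = 0.0845 and 0.0579).

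**Figure D2:**
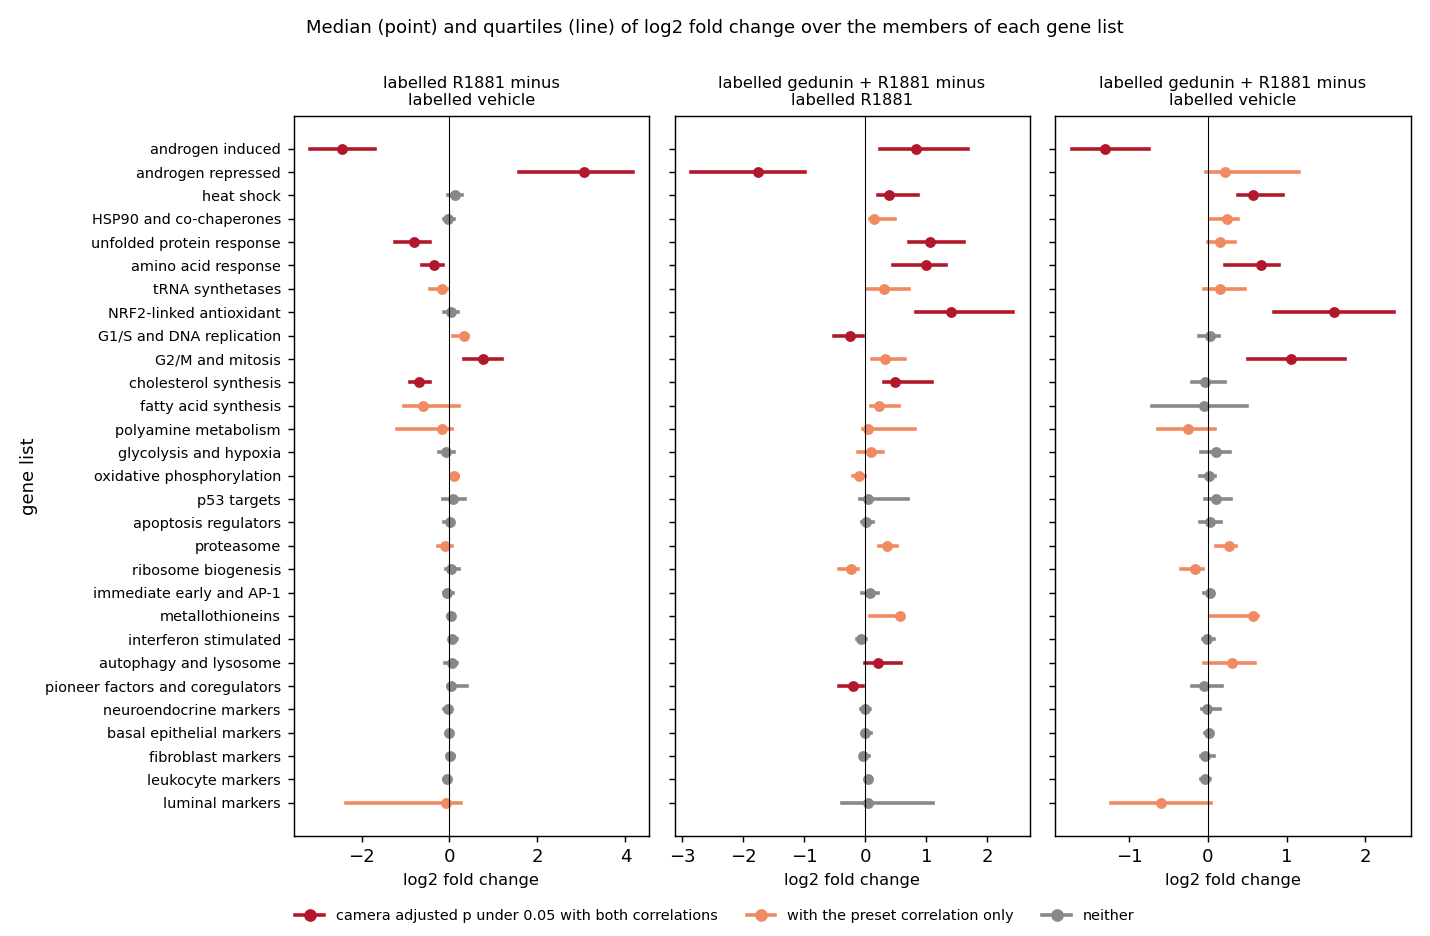
Median (point) and quartiles (line) of log2 fold change (horizontal axis) over the measured members of 29 gene lists (vertical axis) in the 3 comparisons, 1 panel each, with axes scaled separately. Dark red marks lists with a camera adjusted p under 0.05 with the preset and the estimated correlation, orange the preset only, and grey neither; the androgen-induced list lies at -2.45, 0.83 and -1.31.

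The second comparison asks what gedunin does in the presence of androgen, and sets the gedunin arrays against the arrays labelled R1881. If the 6 h in the titles of the latter holds, the length of treatment differs too and cannot be told apart from gedunin. This limit carries over to every result that uses the arrays labelled R1881. No group received gedunin alone. HMOX1, the gene of haem oxygenase 1, rose from 44.0 ± 3.34 to 2280 ± 507 (intensity, mean ± SD, n = 3), 51.1-fold. GDF15, a stress-induced cytokine, rose 12.3-fold, the cystine transporter gene SLC7A11 11.7-fold and GCLM, the modifier subunit of glutamate-cysteine ligase, 8.57-fold. The aldo-keto reductase genes AKR1C2 and AKR1C1 rose 12.6-fold and 10.5-fold, though their probe sets cannot fully separate these paralogs. CAMK2N1 was 37.3-fold lower on the gedunin arrays and PEG3 26.8-fold lower, and GASK1B measured 64.1 ± 8.80 there against 1020 ± 65.9 (n = 3). The lower group of HMOX1, SEC24D, MMP16 and MYRIP lay under the lowest array median, so their folds are approximate too. If the labels vehicle and R1881 were exchanged, the third comparison would be the one that shows gedunin in the presence of androgen. Medians in the second and the third comparison were 1.06 and 0.16 for unfolded protein response genes, 0.48 and -0.03 for cholesterol genes and 0.83 and -1.31 for androgen-induced genes. They were 1.41 and 1.60 for NRF2-linked genes and 0.39 and 0.57 for heat shock genes.

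By limma with Benjamini-Hochberg adjustment, 3277 genes differed, 1676 higher and 1601 lower on the gedunin arrays, of which 197 and 100 changed at least 2-fold. HMOX1 had a log2 fold change of 5.67 ± 0.13 (SE, adjusted p = 7.4e-12). TRIM16 (2.99), SEC24D, a COPII coat subunit (2.67), and ATF3, a stress-induced transcription factor (2.51), were also among the largest rises. Further large falls were MANEA (-3.18), MMP16, a membrane-type matrix metalloproteinase (-3.01), UGT2B17 (-2.89), BCHE (-2.86), DDC (-2.80), MYRIP (-2.73) and ACP3, the gene of prostatic acid phosphatase (-2.61). CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.70 and MYC was 3.03-fold lower. Here the probe set furthest from the value used was at 0.14 for AKR1C1, 0.27 for GDF15, 0.04 for SEC24D, -0.80 for MMP16, -0.25 for DDC, 0.12 for ME1, -0.16 for GATA2, -1.79 for RRM2, -0.08 for TYMS and 0.87 for VEGFA. The KLK2 probe sets ran from 0.74 to 3.70, and the other TMPRSS2 probe set rose less than the one used.

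All 22 measured NRF2-linked antioxidant genes rose, also 22 adjusted over the list alone (median 1.41, camera adjusted p = 2.13e-28). ATF4-linked amino acid synthesis and transport genes rose in 24 of 25 members and fell in 0, also 24 and 0 adjusted over the list alone (median 1.00, camera adjusted p = 8.16e-23), with SLC3A2 at 2.12 and NUPR1 at 1.44. Unfolded protein response genes rose in 23 of 24 and fell in 0, also 23 and 0 adjusted over the list alone (median 1.06, camera adjusted p = 4.55e-26). They included DNAJB9 (2.19), CRELD2 (2.00), MANF (1.81) and DDIT3, the gene of the transcription factor CHOP (1.35 ± 0.08, SE). Heat shock genes rose in 15 of 22 members and fell in 0, 17 and 1 adjusted over the list alone (median 0.39, camera adjusted p = 5.03e-10). DNAJB4 (1.64), the co-chaperone gene BAG3 (1.49), HSPB8 (1.32), HSPB1 (1.03), DNAJB1 (0.90) and HSP90AA1, the inducible HSP90 gene (0.74), rose, as did the constitutive gene HSP90AB1 by 0.31. HSP90 paralogs and co-chaperones had 9 of 19 higher and 1 lower, also 9 and 1 adjusted over the list alone (camera adjusted p = 7.2e-05, adjusted p = 0.111 with an estimated correlation). Of the tRNA synthetases 10 of 16 were higher and 1 lower, also 10 and 1 adjusted over the list alone (camera adjusted p = 1.21e-05, adjusted p = 0.074 with an estimated correlation), led by GARS1 (1.27) and CARS1 (1.21).

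**Figure D3:**
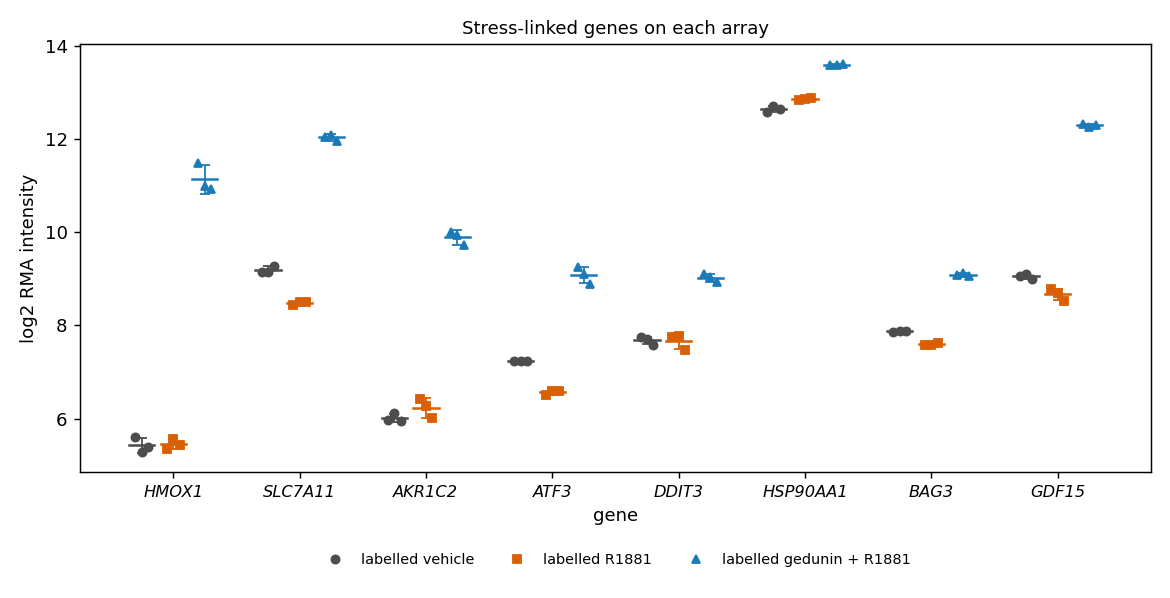
Log2 RMA intensity (vertical axis) of 8 stress-linked genes (horizontal axis) on each of the 9 arrays, with points for arrays, long bars for group means and error bars for the SD (n = 3). For every gene drawn, the 3 gedunin arrays lie above the 6 others; HMOX1 averages an intensity of 2280 on the gedunin arrays and 44.0 on the arrays labelled R1881.

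Androgen-induced genes were higher on the gedunin arrays than on the arrays labelled R1881 in 26 of 36 members and lower in 1, also 26 and 1 adjusted over the list alone (median 0.83, camera adjusted p = 5.23e-18). KLK2 rose by 2.68, KLK3 by 2.43, GNMT by 2.38, TMPRSS2 by 2.35 and FKBP5 by 1.42. The rise of FKBP5 is approximate, since its mean on the arrays labelled R1881 lay under the lowest array median. Androgen-repressed genes were lower in 10 of 12 and higher in 0, also 10 and 0 adjusted over the list alone (median -1.76, camera adjusted p = 1.53e-15). The score of the induced list was 7.59 ± 0.055 on the gedunin arrays (SD, n = 3), 0.94 above the arrays labelled R1881, with an exact two-sided permutation p of 0.1, the smallest possible. Pioneer factors and coregulators of steroid receptors had 7 of 16 lower and 1 higher, 9 and 1 adjusted over the list alone (median -0.20, camera adjusted p = 0.00135), with HOXB13 at -1.08 and GATA2 at -0.80.

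Replication genes fell in 18 of 37 members and rose in 0, also 18 and 0 adjusted over the list alone (median -0.25, camera adjusted p = 6.04e-07), with RRM2, a ribonucleotide reductase subunit, at -1.09, TYMS at -0.89 and MCM6 at -0.73. Mitosis genes rose in 25 of 44 and fell in 4, 28 and 4 adjusted over the list alone (median 0.33, camera adjusted p = 1.4e-08, adjusted p = 0.074 with an estimated correlation). CKS2 (1.17), HMMR (1.13) and NEK2 (1.03) rose while CDK1, the mitotic cyclin-dependent kinase, fell by 1.10. Cholesterol genes rose in 14 of 18 and fell in 1, 15 and 1 adjusted over the list alone (median 0.48, camera adjusted p = 8.59e-10), with INSIG1 at 1.88, IDI1 at 1.57 and HMGCS1 at 1.51. Fatty acid synthesis genes rose in 7 of 13 and fell in 2, 8 and 2 adjusted over the list alone (camera adjusted p = 0.000416, adjusted p = 0.0866 with an estimated correlation), with ME1, malic enzyme, at 2.48. Polyamine genes rose in 4 of 11 and fell in 0, 5 and 0 adjusted over the list alone (camera adjusted p = 0.00709, adjusted p = 0.0993 with an estimated correlation). Proteasome subunits rose in 25 of 30 and fell in 2, 25 and 3 adjusted over the list alone (median 0.36, camera adjusted p = 3.77e-10, adjusted p = 0.0993 with an estimated correlation), led by PSMD8 (0.98) and PSMA3 (0.70). Nucleolar and ribosome biogenesis genes fell in 13 of 23 and rose in 0, 15 and 0 adjusted over the list alone (median -0.24, camera adjusted p = 8.67e-07, adjusted p = 0.0672 with an estimated correlation), among them MYC and RRS1 (-0.60). Respiratory chain subunits fell in 21 of 60 and rose in 0, 23 and 0 adjusted over the list alone (median -0.10, camera adjusted p = 5.78e-05, adjusted p = 0.32 with an estimated correlation). Glycolysis and hypoxia-linked genes rose in 9 of 27 and fell in 2, 11 and 3 adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.326 with an estimated correlation), with VEGFA at 1.60 and P4HA2 at 1.35.

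In this comparison 20 of 29 lists passed camera, 15 higher and 5 lower, and 10 passed with an estimated correlation: the androgen-induced, androgen-repressed, heat shock, unfolded protein response, amino acid, NRF2, replication, cholesterol, autophagy and coregulator lists. With the estimated correlation their camera adjusted p was 0.0171, 0.00128, 0.00284, 0.000585, 0.00128, 0.00162, 0.0456, 0.0212, 0.0374 and 0.0374 in this order.

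The study's design asks how much of the androgen response gedunin reverses; here this is the difference between the groups labelled R1881 and vehicle. Of the 2000 genes higher on the arrays labelled R1881 than on those labelled vehicle, 983 (49.2%) were lower on the gedunin arrays than on the arrays labelled R1881, among them CAMK2N1, PEG3, GASK1B, MANEA, UGT2B17, BCHE and DDC. Of the 1624 lower genes, 874 (53.8%) were higher on the gedunin arrays, among them KLK2, KLK3, TMPRSS2, FKBP5, DNAJB9 and INSIG1. Independent lists would share 267.7 and 227.5 genes. A further 209 genes were higher in both comparisons and 107 lower in both, against 280.2 and 217.3 for independent lists. Both comparisons use the arrays labelled R1881: in 100 simulations with no effects the overlap reached 0 genes, and the covariance of the log2 fold changes was -0.087 against a simulated -0.0027 (r = -0.59 against -0.5, across genes). Without effects few genes are called at all, so the simulated overlap of 0 does not measure what sharing adds among genes that differ. The 3 shared arrays cannot be split into parts of at least 2 arrays each, so part of the excess over independent lists can come from the shared arrays. With genes chosen on 2 arrays per group and measured on the arrays left out, the slope of gedunin minus labelled vehicle on labelled R1881 minus labelled vehicle was 0.489 ± 0.014 (mean ± SD of 3 folds, range 0.473 to 0.501, 2561 to 2939 genes). Both differences subtract the same vehicle array, which alone gives a slope of 0.5 in simulations with no effects, so this slope by itself does not measure a response. In a test added after the data had been seen, the differences were taken from separate vehicle arrays, neither used to choose the genes. The slope was then 0.478 ± 0.016 (mean ± SD of 3 folds), against a simulated 0.001 with no effects. Each fold used all 3 arrays labelled vehicle, so this SD leaves out the spread among them. Also added after the data had been seen was the reversal with the labels vehicle and R1881 exchanged, which asks how many genes differ from the arrays labelled vehicle in the same direction on the arrays labelled R1881 and on the gedunin arrays. It held 1755 genes, 955 (47.8%) of the 2000 and 800 (49.3%) of the 1624, where independent lists would share 300.9 and 192.6. These comparisons share the arrays labelled vehicle, which can likewise add to the excess. The covariance of their log2 fold changes was 0.0848 against a simulated 0.0027 (r = 0.58 against 0.5, across genes).

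The third comparison asks how far cells given both compounds stayed from cells labelled vehicle. HMOX1 was 52.1-fold higher on the gedunin arrays (log2 fold change 5.70 ± 0.13, SE, adjusted p = 7.06e-12 by limma), AKR1C2 14.7-fold, ACKR3 14.1-fold, AKR1C1 11.7-fold and TRIM16 10.2-fold. The lower group of HMOX1, ACKR3 and ORM1 lay under the lowest array median, so their folds are approximate. FKBP5 was 15.0-fold lower, NCAPD3 and ORM1 both 10.5-fold, PAK1IP1 10.1-fold and EAF2 8.90-fold. KLK3 was 1.64-fold lower, KLK2 3.15-fold and TMPRSS2 3.31-fold. With Benjamini-Hochberg adjustment 3219 genes differed, 1800 higher and 1419 lower, of which 141 and 123 changed at least 2-fold. Other probe sets were as low as 0.06 for AKR1C1, and ran from -3.00 to -0.56 for MAF and from -1.77 to -0.95 for KLK2.

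Androgen-induced genes were lower on the gedunin arrays than on the arrays labelled vehicle in 35 of 36 members and higher in 0, also 35 and 0 adjusted over the list alone (median -1.31, camera adjusted p = 6.74e-34), with MAF at -3.00 and LIFR at -2.83. The score of this list was 1.41 lower than on the arrays labelled vehicle, with an exact two-sided permutation p of 0.1, the smallest possible. Androgen-repressed genes had 6 of 12 members higher and 2 lower, 8 and 2 adjusted over the list alone (median 0.22, camera adjusted p = 0.00731, adjusted p = 0.0752 with an estimated correlation), with BCHE at 1.46 and PEG3 at -1.51. Luminal markers were lower in 8 of 12 members and higher in 3, also 8 and 3 adjusted over the list alone (median -0.60, camera adjusted p = 0.000758, adjusted p = 0.137 with an estimated correlation), with ACP3 at -2.73 and KRT8 at -1.59.

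NRF2-linked genes were higher in 21 of 22 members and lower in 0, also 21 and 0 adjusted over the list alone (median 1.60, camera adjusted p = 1e-28), with SLC7A11 at 2.84. Heat shock genes were higher in 20 of 22 and lower in 0, also 20 and 0 adjusted over the list alone (median 0.57, camera adjusted p = 1.63e-14), with DNAJB4 at 1.73, HSPB8 at 1.62, HSPB1 at 1.53, BAG3 at 1.21 and HSP90AA1 at 0.95. Amino acid genes were higher in 19 of 25 and lower in 2, also 19 and 2 adjusted over the list alone (median 0.67, camera adjusted p = 4.58e-12), with ATF3 at 1.85 (3 equal values on the arrays labelled vehicle) and DDIT3 at 1.35. Unfolded protein response genes were higher in 12 of 24 and lower in 4, also 12 and 4 adjusted over the list alone (median 0.16, camera adjusted p = 0.00618, adjusted p = 0.0723 with an estimated correlation). Mitosis genes were higher in 38 of 44 and lower in 0, 39 and 0 adjusted over the list alone (median 1.05, camera adjusted p = 4.51e-31). HMMR rose by 2.39, CKS2 by 2.35, DLGAP5 by 2.18 (approximate, from a dim group as above) and CDC20, the activator of the anaphase-promoting complex, by 2.18. Of 37 replication genes 5 were higher and 6 lower, also 5 and 6 adjusted over the list alone (median 0.03, camera adjusted p = 0.863), and of 18 cholesterol genes 5 were higher and 6 lower, also 5 and 6 adjusted over the list alone (median -0.03, camera adjusted p = 0.869).

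Here 15 of 29 lists passed camera, 11 higher and 4 lower, and 5 passed with an estimated correlation: the androgen-induced, heat shock, amino acid, NRF2 and mitosis lists. With the estimated correlation their camera adjusted p was 0.00457, 0.00329, 0.00457, 0.00329 and 0.00836 in this order. The polyamine list lost its call without vehicle replicate 2 (adjusted p = 0.072).

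A count that does not depend on which of the other 2 groups is which was added after the data had been seen. On the gedunin arrays 840 genes were higher than in both other groups and 546 lower, of which 59 and 15 differed at least 2-fold from both. The higher genes included HMOX1, AKR1C2, SLC7A11, GDF15, DDIT3, HSP90AA1, BAG3, CDKN1A, CKS2 and HMMR, and the lower genes included MYC, RRM2, HOXB13 and PEG3. Independent lists would share 252.2 and 189.9 genes. Both underlying comparisons use the 3 gedunin arrays, too few to split into parts of at least 2 arrays each: in 100 simulations with no effects the overlap reached at most 1 gene, and the covariance of the log2 fold changes was 0.0382 against a simulated 0.0027 (r = 0.31 against 0.5, across genes). Part of the excess over independent lists can come from these shared arrays. The simulated overlap does not measure that part, because few genes are called where there are no effects. In the moderated F-test over the 3 groups, 4698 of 11963 genes (39.3%) differed.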

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

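The count of probe sets apart from both other groups, and in the weighing of the labels the tests of a single exchanged array per group and of array scaling, were chosen only after the result was seen.

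Probe sets without a single gene symbol entered no comparison of genes, yet some stood apart on the gedunin arrays, called by limma in the same direction against both other groups. This held for 109 of 1043 probe sets with several symbols, 44 higher and 65 lower. It also held for 95 of 2108 probe sets with no symbol in the annotation, 56 higher and 39 lower. Of those without a symbol, 1 probe set had a log2 fold change of 2.76 ± 0.07 (SE) against the arrays labelled R1881 and 3.43 ± 0.07 against those labelled vehicle, and another had -2.06 ± 0.15 and -1.78 ± 0.15. Their identity was not analysed here.

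The androgen-induced genes were lower and the androgen-repressed genes higher on the arrays labelled R1881 than on those labelled vehicle. An exchange of a single array per group is argued against by the scores of the induced list, since the lowest array labelled vehicle lay 2.29 above the highest array labelled R1881 on the log2 scale, with a largest SD within these groups of 0.053. A difference in array scaling is argued against because the medians of the repressed and induced lists lay 5.52 apart with opposite signs. Both tests use the lists that define the pattern, so neither is independent evidence. A candidate explanation that stays open is that the labels vehicle and R1881 were exchanged for all 3 arrays of both groups: a second list of androgen-induced genes, not looked at before, had a median of -0.82 with 33 of 41 members lower and 1 higher (camera p = 1.27e-21, p = 7.41e-05 with an estimated correlation). A fall of these genes under R1881 in these cells was not tested and also stays open, though it would be opposite to the response described for them. The lists would have the same values under both explanations, so they cannot tell these apart. The 6 h in the titles of the arrays labelled R1881 is argued against as the cause for the first 2 lists. A shorter exposure would leave a smaller response and not an opposite one. Of the induced list 34 of 36 members were lower and 0 higher (median -2.45). Of the repressed list 10 of 12 were higher and 0 lower (median 3.07).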

How the results depend on the processing

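The exchange of the labels, the slopes by direction, the slopes with separate vehicle arrays and the count of genes apart from both other groups were chosen only after the data had been seen. All counts of called genes kept within 1.5 times of their value under every alternative except the fold threshold, with which 397, 297 and 264 genes were called in the first, the second and the third comparison, 150 were reversed and 74 stood apart from both other groups; the stricter rule itself lowers these counts. With single arrays left out, the comparisons called 3171 to 3554, 2823 to 3302 and 2764 to 3401 genes, the reversal held 1637 to 1830 and the genes apart 1152 to 1399. Replicate numbers did not pair the arrays: residuals of same-numbered arrays correlated between -0.107 and 0.133, and 1 of 9 arrays correlated best with its own number in both other groups. With the replicate number as a block, 3576, 3210 and 3178 genes were called, of which 3475, 3129 and 3072 were called without it. Camera with an estimated correlation left 6, 10 and 5 lists; it changes both the correlation within lists and the degrees of freedom of the test, which were not taken apart. Fry, which unlike camera does not set a list against the other genes, called 22, 26 and 20 lists. How much this difference adds was not tested. Fry turned the direction of the autophagy list in the first comparison, which camera had not called (fry adjusted p = 0.00496, camera adjusted p = 0.976). The median of its members was 0.045 but their mean -0.12, so the direction depends on how the members are combined. Without the dimmest genes, camera lost the proteasome (adjusted p = 0.0733) and luminal lists (0.211) in the first comparison, and in the third the HSP90 and tRNA synthetase lists (both 0.0638), the polyamine list (0.0829) and the androgen-repressed list (0.0518). With the mean of all probe sets of a gene it lost the proteasome list (0.0929) and gained the heat shock list (0.0325) in the first comparison, and gained the glycolysis list in the third (0.0461). The difference in androgen-induced score moved to -2.23, 0.90 and -1.33 with the mean of probe sets and to -2.11, 0.85 and -1.27 with the offset of 16, which shrinks folds of dim genes. With the labels vehicle and R1881 exchanged it became 2.35, -1.41 and 0.94, by construction. The slope was 0.583 over androgen-induced members, for which the cause was not tested, and 0.511 with the labels exchanged, by construction. It was 0.444 and 0.522 over genes higher and lower on the arrays labelled R1881, and 0.422 and 0.519 with separate vehicle arrays for both differences; tests of this gap left its cause open. Over 339 results for named genes, 12 lost their call under some alternative, 1 gained one and 0 reversed. Over 87 list results, 27 lost the call under some alternative, 19 gained one and 1 reversed. No signal from background probes was used, so a limit of detection cannot be given.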

Other observations

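In this part, the test of a larger share of cycling cells and the slopes by direction, also with separate vehicle arrays, were chosen only after the result was seen.

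Members of further gene lists also moved on the gedunin arrays, but of the lists in this paragraph and the next only the autophagy list passed camera with both correlations, and only against the arrays labelled R1881. Metallothionein genes, near-identical paralogs that bind zinc and copper, rose in 5 of 8 members and fell in 0 against the arrays labelled R1881, also 5 and 0 adjusted over the list alone (median 0.57, camera adjusted p = 0.000396, adjusted p = 0.0993 with an estimated correlation), with MT2A at 0.64 and MT1G at 0.60. Against the arrays labelled vehicle the counts were also 5 and 0. Autophagy and lysosome genes rose in 13 of 23 members and fell in 0 against the arrays labelled R1881, 14 and 0 adjusted over the list alone (median 0.21, camera adjusted p = 8.38e-06). They included NPC1, a lysosomal cholesterol transporter (1.84, another probe set 0.28), the autophagy receptor gene SQSTM1 (1.68) and GABARAPL1 (1.09). WIPI1, which acts in autophagosome formation, rose by 1.09 against the arrays labelled R1881 and fell by 1.88 against those labelled vehicle. Against the latter the autophagy list lost its call with an estimated correlation (camera adjusted p = 0.00031, adjusted p = 0.0752 with an estimated correlation).

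Of the p53 targets, 6 of 17 rose and 1 fell on the gedunin arrays against those labelled R1881, also 6 and 1 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.071), though it did without R1881 replicate 3 (adjusted p = 0.0481). GDF15 rose by 3.62 and GADD45A, a growth arrest gene, by 0.82, while SESN1 fell by 2.00. Of 25 apoptosis regulators 5 rose and 2 fell, also 5 and 2 adjusted over the list alone (camera adjusted p = 0.287), with BNIP3 at 1.11 and PMAIP1, which encodes NOXA, at 0.75. Of 21 immediate early genes 5 rose and 1 fell, also 5 and 1 adjusted over the list alone (camera adjusted p = 0.261), with KLF6 at 1.06 (probe sets from -0.06 to 1.28) and DUSP1 at 0.87. Of 22 interferon-stimulated genes 0 rose and 5 fell, also 0 and 5 adjusted over the list alone (camera adjusted p = 0.173), with ISG15 at -0.60. Single genes from the marker lists moved while the lists did not pass camera. Fry called the neuroendocrine list in the first and second comparisons (fry adjusted p = 8.21e-06 and 2.31e-05). It also called the fibroblast list there (fry adjusted p = 0.00504 and 0.01). NTS, the neurotensin gene, was at 1.74 and FN1, the fibronectin gene, at 1.91 on the arrays labelled R1881 against those labelled vehicle. Both were lower on the gedunin arrays than on those labelled R1881, at -1.37 and -1.29. The 6 probe sets of FN1 ran from 0.30 to 1.91 and from -1.33 to -0.21 in these comparisons.

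On the gedunin arrays, mitosis genes were higher than on the arrays labelled R1881 (median 0.33), a call that was lost with an estimated correlation (camera adjusted p = 0.074), while replication genes were lower. Against the arrays labelled vehicle the mitosis median was 1.05 but the replication median 0.03, with 5 genes higher and 6 lower (camera adjusted p = 0.863), so the opposite directions held against only 1 of the other groups. A bias with signal brightness is argued against, since the mitosis median lay at percentile 100 of 10000 random lists matched on mean signal, whose largest median was 0.12. A larger share of cycling cells would raise both lists, so alone it does not account for the replication median of -0.25 (camera adjusted p = 6.04e-07, adjusted p = 0.0456 with an estimated correlation). This median is part of the pattern itself and so is not independent evidence. A larger share beside a separate fall of replication genes cannot be told apart here. Other effects of gedunin on the cell cycle were not tested and stay open.

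The gedunin arrays lay nearer to the arrays labelled vehicle for genes higher on the arrays labelled R1881 (slope 0.444) than for genes lower there (slope 0.522), a difference of 0.078 with 0.027 to 0.151 in the 3 folds. With separate vehicle arrays for both differences the slopes were 0.422 and 0.519. A gedunin response added to both sets stays open: the difference was 0.132 without genes apart from both other groups, but that filter picks genes by the compared quantity, so the test cannot decide. Compression of bright or dim signals may contribute too and cannot be told apart, because with group means kept between log2 values of 6 and 11 the difference was -0.025, with folds from -0.107 to 0.079.

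The 6 arrays of each comparison can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split called 3624, 3277 and 3219 genes in the first, the second and the third comparison against 0 in the highest other split of each, and 13, 20 and 15 lists against 9, 17 and 11. For each of these, 1 split, the real one, reached the real value. Among 100 drawn splits of the 9 arrays, the real one included, only the real split reached the 4698 genes of the F-test (highest other 1259). Chance is therefore unlikely for this count, at a share of 1 in 100, the smallest these splits allow. The splits cannot tell treatment from another difference that follows the groups. For the 1857 reversed genes and the 1386 genes apart from both other groups, the highest other splits drawn reached 948 and 1079. No split that only exchanges whole groups was among those drawn. With vehicle and R1881 exchanged, the genes apart again number 1386. These 2 counts therefore show that the arrays fall into 3 groups, but do not set the real labels apart from other labels on the same groups.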
